A study of Mus musculus with 16 samples.

How the data were processed

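The study measured messenger RNA and its N6-methyladenosine (m6A, a methyl group on internal adenosines of RNA) in mouse bone after ovariectomy, the removal of the ovaries, or a sham operation. Per the labels, 16 libraries were made from wild type animals, with 4 input and 4 immunoprecipitated (IP) libraries in each arm. An IP library holds RNA fragments pulled down with an antibody to m6A, and an input library holds the RNA before the pull-down. Libraries titled NC were taken as the sham arm and those titled OVX as the ovariectomy arm. The labels conflict for the IP libraries: the treatment field reads ovariectomy for all 8, including the 4 titled NC, and the title was used. The labels' protocols describe a stranded mRNA kit with unique molecular identifiers. The labels number the libraries 1 to 4 in each arm and do not say whether each came from a separate animal, so p-values may measure technical spread.

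Both tables analysed here hold the authors' own comparisons and no value for a single library. The submitters' processing notes name HISAT2, StringTie, DESeq and the rat genome build rn6, without versions or roles. The samples are mouse, and 13000 of the 13026 peaks whose gene symbol is in the GRCm38.p6 RefSeq annotation (99.8%) lay inside the gene of that name on that build. Of the RNA table's symbols, 25041 (99.2%) were in the same annotation. Peak coordinates are printed as the peak table gives them, counted from 1, and none were taken from the annotation.

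In the RNA table, per the file headers, the authors deposited a mean over libraries of counts divided by size factors (a normalized count signal), a log2 fold change with its standard error (SE), a Wald statistic score, a p-value and an adjusted p-value for each gene. The Wald statistic equalled the ratio of the fold change to its SE. The deposited adjusted p-values equalled Benjamini-Hochberg values over the 15396 genes that have one, and the lowest mean count among these was 12.4. In the peak table, per the file headers, the authors deposited the p-value of each peak against input, log10 values of that p and of its false discovery rate (FDR), and the fold enrichment of IP over input as a ratio. It also holds the log2 difference of enrichment between the arms, with log10 values of its p and FDR as a score, as deposited. The peak caller and whether replicates were pooled are not given in the sources used here.

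Neither table says which arm is the numerator of its fold changes, and that arm may differ between the tables. Signs are therefore given as deposited, as positive or negative, and not as higher or lower after ovariectomy. By the usual alphabetical order of group names NC would be the denominator, and a positive value would then mean a higher level after ovariectomy, but the tables do not record this.

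No per-gene test was run here, because no per-library counts or values were at hand. Genes with a deposited adjusted p under 0.05 were counted as changed, and peaks with a deposited difference p under 0.05. The design fixed before the data were examined had planned a count model, a principal component analysis, left-out libraries, a replicate block and set tests with an estimated correlation, and none of these could be run. The 31 gene lists fixed beforehand were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald statistics of genes with an adjusted p. The preset inter-gene correlation was 0.01, and p-values were adjusted by the Benjamini-Hochberg method over 30 lists. The list of mitochondrially encoded genes had 0 of its 13 members in the RNA table and could not be tested. Lists were compared with m6A calls, and m6A calls with RNA calls, by two-sided Fisher's exact tests in scipy 1.17.1, with numpy 2.4.6 and pandas 2.3.3 on Python 3.11.15. A Mantel-Haenszel odds ratio within 10 classes of the mean count came from statsmodels 0.14.6. Shares have exact 95% binomial intervals and numbers exact 95% Poisson intervals, which cover counting error only. Figures were drawn with matplotlib 3.10.9.

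The rule for named genes, fixed beforehand, took up to 8 genes per direction with the largest fold change among changed genes with a mean of at least 10 counts, leaving out predicted genes and antigen receptor segments. Its condition that the values of the arms must not overlap could not be applied without per-library values. From each list, up to 4 changed members were taken by smallest p, and for a list with none the 2 members with the smallest p. Of the peaks, the 6 with the smallest difference p in each direction were named, with called peaks in the m6A, bone and Wnt lists. For the overlap with RNA, up to 4 genes per combination of signs were taken. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

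The depth of single libraries is not in the tables. The lowest mean counts were whole multiples of 8 smallest steps, each worth 1 count in 1 library, and these steps give the size factors. The steps were found as values shared by at least 4 genes after rounding to 1e-07. The scripts were tested on simulated data. With Wald statistics of 15396 genes drawn independently, 98% of 100 lists shifted by 2 were recovered and 1.39% of 432 unshifted lists were called. These rates do not cover lists whose members are correlated, as real ones can be. All 8 steps were recovered from 3000 simulated low mean counts. With 15396 simulated genes, Benjamini-Hochberg adjustment recovered 39.0% of genes shifted by 3 SE and 100% of those shifted by 6 SE, with 6.85% of calls false. Alternatives were other thresholds and filters, another preset correlation, ranks, subsets of peaks, and another choice of the peak or RNA threshold in the overlap.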

Results

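RNA and its m6A methylation were profiled in mouse bone after ovariectomy, a model of the bone loss that follows loss of estrogen, and after a sham operation. The series asks how m6A relates to osteoporosis. There were 4 input and 4 IP libraries in each arm, 16 in all. The authors' deposited table of RNA comparisons listed 25239 genes, of which 6190 had a mean count of 0, and its mean normalized counts summed to 43717045. Low counts in a single library were most often 4, in 284 of the 955 genes where they could be read. The 8 size factors read from its lowest counts lay between 0.867 and 1.24. The 4 steps of genes with positive fold changes gave a mean size factor of 1.03 ± 0.191 (SD over 4 steps), and the 4 of genes with negative fold changes gave 0.998 ± 0.103, a difference within the spread (two-sided exact permutation p = 0.743). Fold changes are log2 values ± SE with their sign as deposited, since which arm is the numerator is not stated.

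B cell genes had positive fold changes, and genes of interferon response, cell division and red cells were positive as groups. Skeletal muscle, marrow stroma, endothelium, nerve sheath and mitochondrial respiration were negative as groups. Dntt, which adds nucleotides at antigen receptor joints, had a fold change of 2.34 ± 0.24 in the authors' deposited table (adjusted p = 2.6e-19). Isg15, an interferon-induced ubiquitin-like protein, stood at 1.54 ± 0.20 in the authors' deposited table. Greb1, an estrogen receptor target, stood at -2.35 ± 0.65 in the authors' deposited table. In total, 1875 of 15396 tested genes (12.2%) had an adjusted p under 0.05 in the authors' deposited table, 934 positive and 941 negative. Positive calls in the authors' deposited table had a median of 0.43 (median SE 0.11) and negative calls a median of -0.72 (median SE 0.20). With an absolute log2 fold change of at least 1, the authors' deposited table held 94 positive and 298 negative calls.

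The B cell list had the smallest p of the lists, with 14 of 18 members past the threshold, 15 when adjusted over the list alone, and all 18 positive in the authors' deposited table. Its median fold change was 1.06 (cameraPR adjusted p = 6.2e-23). The surrogate light chain genes Vpreb1 and Igll1, which form the receptor of B cell precursors, had values of 2.53 ± 0.32 and 3.07 ± 0.51 in the authors' deposited table. Rag1 and Rag2, the recombinase that joins antigen receptor genes, stood at 2.22 ± 0.39 and 2.76 ± 0.42 in the authors' deposited table. Cd79a and Cd79b, the signalling chains of the B cell receptor, stood at 1.07 ± 0.22 and 0.95 ± 0.24 in the authors' deposited table. The plasma cell list was split in the authors' deposited table, where 2 of 8 members passed with a positive sign and 2 with a negative one, 2 and 2 also when adjusted over the list alone. Jchain, the joining chain of secreted antibody, stood at -0.82 ± 0.14 and Irf4 at 1.09 ± 0.22 in the authors' deposited table. The plasma cell list as a whole missed the threshold (cameraPR adjusted p = 0.745), with 3 of 8 members positive and 5 negative.

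**Figure D1:**
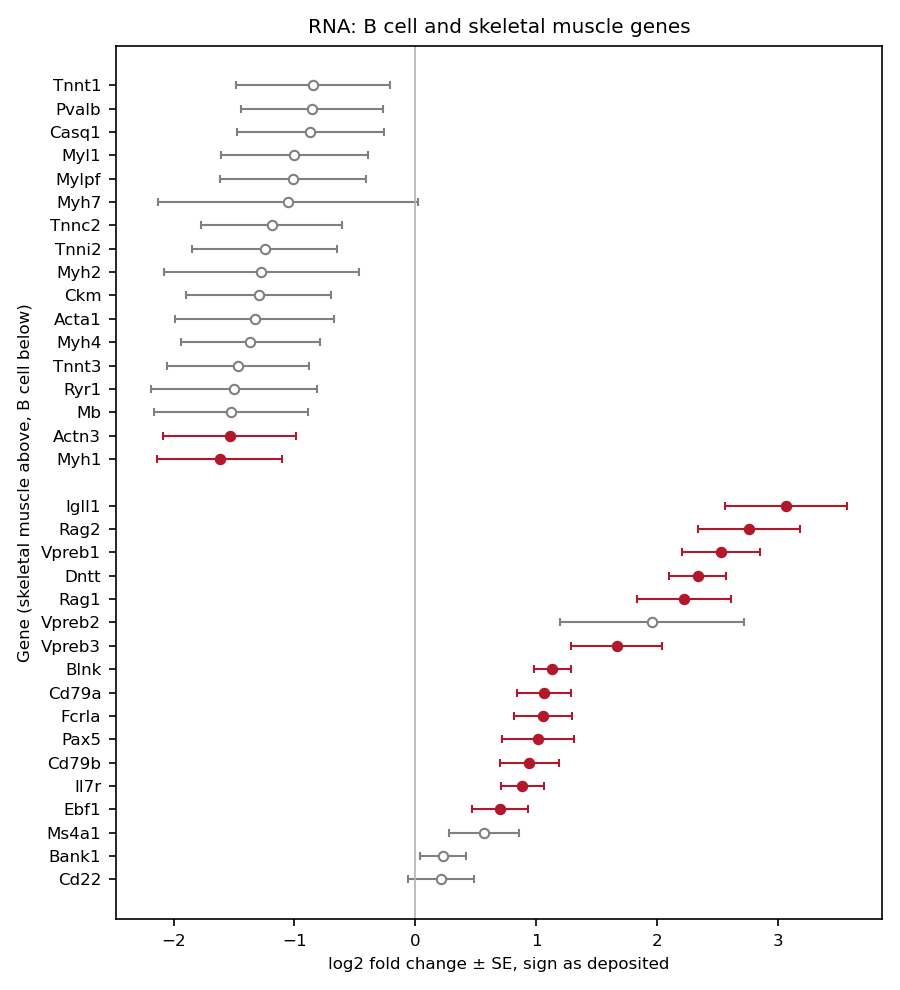
Deposited log2 fold change (horizontal axis, points) with its standard error (bars) for 17 of the 18 B cell genes and the 17 skeletal muscle genes. The B cell list had a median of 1.06 and the muscle list a median of -1.28, with longer bars for muscle.

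Of 21 interferon response genes, 20 were positive and 10 of these passed the threshold in the authors' deposited table, 14 when adjusted over the list alone, and the 1 negative gene did not pass. The list's median was 0.65 (cameraPR adjusted p = 9.0e-11). Rsad2, an antiviral enzyme, had 1.12 ± 0.18 and Oas3 had 1.24 ± 0.30 in the authors' deposited table. All 27 proliferation genes were positive and 5 passed in the authors' deposited table, 5 also when adjusted over the list alone (median 0.29, cameraPR adjusted p = 1.4e-07). Ube2c and Plk1, which act in mitosis, stood at 0.44 ± 0.10 and 0.51 ± 0.13 in the authors' deposited table. Of 16 erythroid genes, 13 were positive, of which 5 passed, and none passed with a negative sign in the authors' deposited table, 7 when adjusted over the list alone (median 0.31, cameraPR adjusted p = 1.1e-04). Tfrc, the transferrin receptor, had 0.67 ± 0.13 and Epb42 had 0.63 ± 0.13 in the authors' deposited table. The globin gene Hba-a1, the tested erythroid member with the highest mean count, had 0.003 ± 0.224 in the authors' deposited table. It was chosen after its value was seen. Of 10 megakaryocyte genes, 1 passed in the authors' deposited table, Vwf with 0.41 ± 0.13, and 1 when adjusted over the list alone. That list's call (cameraPR adjusted p = 0.036) was lost at a preset correlation of 0.05 (adjusted p = 0.089).

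Some genes of the m6A machinery passed the threshold, most of them positive and 1 negative. Of 11 writers, 3 passed with a positive sign and none with a negative one in the authors' deposited table, 4 and none when adjusted over the list alone (median 0.08, cameraPR adjusted p = 0.0064). Mettl3, the catalytic methyltransferase, stood at 0.32 ± 0.11, Rbm15 at 0.51 ± 0.09 and Rbm15b at 0.34 ± 0.06 in the authors' deposited table. Among 17 erasers and readers, 3 passed with a positive sign and 1 with a negative one in the authors' deposited table, with 3 and 2 when adjusted over the list alone. The readers Elavl1, Prrc2a and Ythdf2 stood at 0.35 ± 0.06, 0.30 ± 0.06 and 0.23 ± 0.08, and Igf2bp2 at -0.58 ± 0.19 in the authors' deposited table. Neither demethylase passed in the authors' deposited table, where Fto had -0.18 ± 0.07 and Alkbh5 had -0.10 ± 0.14. Adjusted over the list alone, Fto passed with a negative sign beside Igf2bp2. The erasers and readers had a cameraPR adjusted p of 0.036, which became 0.117 at a preset correlation of 0.05, 0.074 with genes of at least 50 mean counts and 0.056 on ranks.

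Skeletal muscle genes were negative throughout, at a median of -1.28 (cameraPR adjusted p = 2.3e-04). Only 2 of 17 members passed in the authors' deposited table, Myh1 with -1.62 ± 0.52 and Actn3 with -1.54 ± 0.55, and 2 when adjusted over the list alone. The list took 2.26% of all mean counts in the authors' deposited table. Its members spread less (SD 0.256) than their median SE of 0.605. So did the members of the proliferation (0.087 and 0.141), endothelial (0.126 and 0.220) and megakaryocyte (0.150 and 0.208) lists. The other called lists spread more than their median SE. Such narrow spreads point to errors shared between members beyond the preset correlation of 0.01. The cameraPR p-values of these narrow lists may therefore be too small. A wider spread does not show that members have independent errors, so p-values of the other lists may be too small as well. Of 27 mitochondrial respiration genes, 25 were negative and 7 of these passed in the authors' deposited table, 10 when adjusted over the list alone, and neither of the positive ones passed (median -0.18, cameraPR adjusted p = 2.2e-04). Ndufs1, a subunit of respiratory complex I, stood at -0.35 ± 0.06 in the authors' deposited table. Skeletal muscle is rich in mitochondria, and its markers moved in the same direction. All 8 nerve and glia genes were negative and 2 passed in the authors' deposited table, among them Prx of the myelin sheath with -1.30 ± 0.44, and 3 passed when adjusted over the list alone (cameraPR adjusted p = 0.011).

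All 12 marrow stroma genes were negative and 4 passed in the authors' deposited table, 4 also when adjusted over the list alone (median -0.38, cameraPR adjusted p = 0.0011). Cxcl12, the chemokine that holds blood stem cells in the marrow, stood at -0.51 ± 0.13 and Lepr at -0.75 ± 0.26 in the authors' deposited table. Of 12 endothelial genes, only Eng passed in the authors' deposited table, with -0.33 ± 0.12, and none when adjusted over the list alone (median -0.36, cameraPR adjusted p = 0.0046). Of 17 marrow adipocyte genes, only Lpl, which releases fatty acids from lipoproteins, passed in the authors' deposited table, with -0.997 ± 0.248 (list median -0.32, cameraPR adjusted p = 0.0099). The count for adipocytes was also 1 when adjusted over the list alone. Of 11 estrogen responsive genes, 9 were negative and 3 of these passed in the authors' deposited table, Greb1, Gata3 with -1.46 ± 0.43 and Igfbp4 with -0.42 ± 0.15, and 3 when adjusted over the list alone. The estrogen list's cameraPR adjusted p of 0.031 became 0.081 at a preset correlation of 0.05.

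No bone cell list passed the threshold as a group in the main setting. Of 20 osteoblast and matrix genes, 10 were positive and 10 negative, and 3 passed, all positive, in the authors' deposited table, with 4 positive and 1 negative past the threshold when adjusted over the list alone. Col1a1, the main collagen of bone, had 1.12 ± 0.32, and the osteocalcin genes Bglap and Bglap2 had 1.08 ± 0.34 and 1.10 ± 0.32 in the authors' deposited table. Bglap and Bglap2 are near-identical copies, and reads could be split between them. The osteoblast list had a median of -0.01, a mean of 0.13 and a positive test direction (cameraPR adjusted p = 0.682). Of 20 osteoclast genes, only Ctsk, the collagen-degrading protease of resorption, passed in the authors' deposited table, with -0.72 ± 0.20, and 1 when adjusted over the list alone (median -0.26, cameraPR adjusted p = 0.197). Of these osteoclast genes, 13 were negative and 7 positive. No osteocyte gene of 12 passed in the authors' deposited table, and none when adjusted over the list alone (median -0.28, cameraPR adjusted p = 0.109). Of the 12 osteocyte genes, 11 were negative. The osteocyte list was called on ranks (adjusted p = 0.046). No gene passed among 10 bone resorption signals or 15 chondrocyte genes in the authors' deposited table, and none when adjusted over each list alone (both cameraPR adjusted p = 0.682).

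Among signalling lists, Wnt had 1 positive and 3 negative genes of 22 past the threshold in the authors' deposited table, the same numbers when adjusted over the list alone. Lef1, a Wnt-responsive transcription factor also active in B cell precursors, had 1.32 ± 0.19, and the Wnt enhancers Rspo2 and Rspo3 had -1.69 ± 0.41 and -0.79 ± 0.24 in the authors' deposited table. The Wnt list had a cameraPR adjusted p of 0.109, and of 0.027 on ranks. BMP and TGF-beta signalling had 1 positive and 4 negative genes of 27 past the threshold in the authors' deposited table, with 1 and 5 when adjusted over the list alone. Fst, an activin antagonist, stood at -1.15 ± 0.31 and Bmpr1a at -0.72 ± 0.20 in the authors' deposited table. Its cameraPR adjusted p of 0.043 became 0.167 at a preset correlation of 0.05, and that of the lysosome list went from 0.048 to 0.167. Of 21 lysosome genes, Ctsl and Lamp1 passed in the authors' deposited table, with -0.52 ± 0.18 and -0.21 ± 0.06, and 1 when adjusted over the list alone. Collagens and matrix enzymes had 1 positive and 2 negative genes of 30 past the threshold in the authors' deposited table, as when adjusted over the list alone (cameraPR adjusted p = 0.281).

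The other lists missed the threshold of the list test. Neutrophil and monocyte genes had none past the threshold among 18 and 17 in the authors' deposited table, and none when adjusted over each list alone (cameraPR adjusted p = 0.281 and 0.967). Of the neutrophil genes 15 were negative and 3 positive, and of the monocyte genes 9 and 8. T and NK cell genes had 1 of 14 past the threshold in the authors' deposited table, Lck with 0.39 ± 0.13, and 1 when adjusted over the list alone (cameraPR adjusted p = 0.967). NF-kB and cytokine genes had 1 of 20 past the threshold in the authors' deposited table, Nfkb2 with 0.38 ± 0.09, and 1 when adjusted over the list alone (cameraPR adjusted p = 0.682). Immediate early genes had 2 positive and 1 negative genes of 20 past the threshold in the authors' deposited table, as when adjusted over the list alone (cameraPR adjusted p = 0.682). Antioxidant genes had 1 positive and 3 negative genes of 21 past the threshold in the authors' deposited table, as when adjusted over the list alone (cameraPR adjusted p = 0.967). The medians of the NF-kB and antioxidant lists, 0.0049 and 0.02, had the opposite sign to their means of -0.07 and -0.01, and the tests pointed positive for NF-kB and negative for antioxidants.

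**Figure D2:**
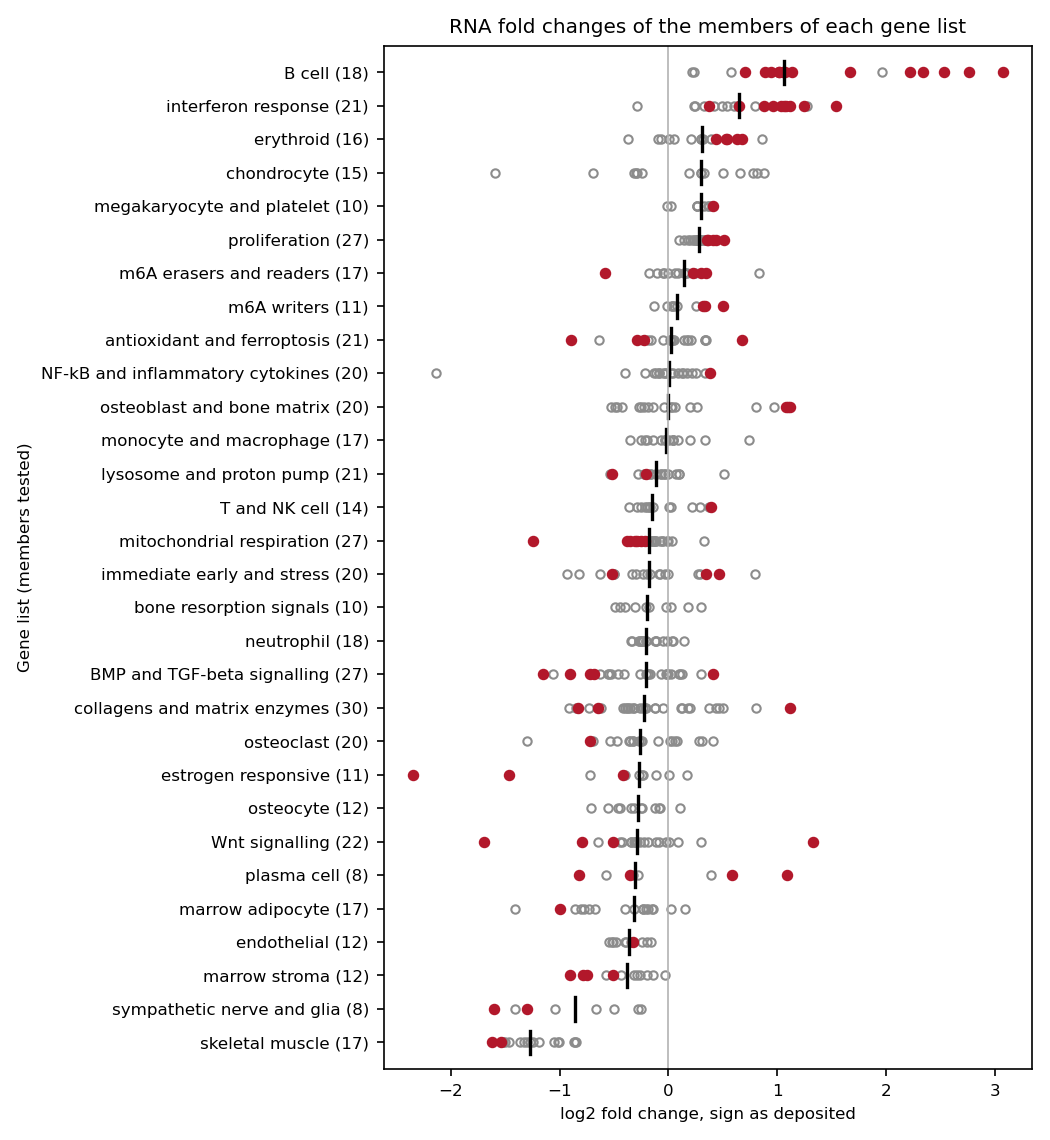
Deposited log2 fold change of each tested member (horizontal axis, points) by gene list (rows), with filled red points at an adjusted p under 0.05 and a black tick at the list's median. The B cell list lies farthest to the positive side with a median of 1.06 and the skeletal muscle list farthest to the negative side with -1.28.

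The largest single fold changes outside these lists were partly of low counts. On the positive side, the authors' deposited table gave Lgr5, a receptor in Wnt signalling, 2.49 ± 0.43, Tifa 2.31 ± 0.44 and Drc7 2.24 ± 0.32. Evi2 had 11.05 ± 2.90 in the authors' deposited table, a fitted value that stands for no fold. At its locus, Evi2a and Evi2b, chosen after their values were seen, had -0.14 and -0.42. On the negative side, the authors' deposited table gave Zic1 -7.11 ± 1.33 at a mean of 12.5 counts and Pet117 -5.03 ± 1.22 at a mean of 158 counts. Tppp2, Mir12191 and Efcab6 had -4.90, -4.64 and -4.27 in the authors' deposited table, at means of 12.8 to 24.6 counts. Fyb2 stood at -3.31 ± 0.69 and the pseudogene Rplp2-ps1, which can share reads with its parent gene, at -4.07 ± 1.01 in the authors' deposited table. Of the genes with a fold change, 34 had no p in the authors' deposited table, led by the globin gene Hbb-bs with a mean count of 66975.

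The authors' deposited table of m6A peaks held 13083 peaks in 6847 genes, of which 3686 (53.8%) had 1 peak. Ttn, the giant muscle protein, carried 35 peaks, Syne1 19, Mki67 18 and Dst 17 in the authors' deposited table, genes chosen after their values were seen. The enrichment over input had a median of 1.82 (quartiles 1.54 and 2.20), and 37.3% of peaks reached 2 in the authors' deposited table. Peaks covered a median of 151 exonic bases (quartiles 101 and 249), and 5252 (40.1%, exact 95% interval 39.3 to 41.0) spanned at least 2 exon blocks in the authors' deposited table. Of all 13083 peaks, 60.6% lay on the plus strand of the genome in the authors' deposited table. The highest enrichments, chosen after their values were seen, were 8.07 in Rnaset2b, 7.62 in Esf1 and 7.01 in Pgp in the authors' deposited table.

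Few m6A differences between the arms stood out. The authors' deposited table held 3 peaks at an FDR under 0.05, in Kif21b, a kinesin motor, Cdk13, a transcription kinase, and Hspd1, a mitochondrial chaperone. The Hspd1 peak (chromosome 1, 55082123 to 55083749) had a log2 difference of -0.43 (log10 p = -5.63) in the authors' deposited table. RNA of Hspd1 was also called in the authors' deposited table, at 0.21 ± 0.06 (adjusted p = 0.0033), and that of Kif21b and Cdk13 was not. The Cdk13 peak (chromosome 13, 17764988 to 17765088) had 0.15 (log10 p = -8.11) in the authors' deposited table. Its difference was also small for its p, below the median absolute value of 0.31 among peaks with p under 0.05. The Kif21b peak (chromosome 1, 136144726 to 136145134) had a log10 p of -434 beside a difference of 0.05 in the authors' deposited table, a p out of proportion to its size. Next by p on the positive side were peaks in Dnajc8, Trim30a, Osbpl9 and Ddx10 with 0.24, 0.43, 0.33 and 0.30 in the authors' deposited table. On the negative side, Lyn, Pagr1a, Rpl6, F5 and Ucp2 had -0.63, -0.78, -0.07, -0.67 and -0.40 in the authors' deposited table.

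At an unadjusted p under 0.05, the authors' deposited table held 644 peaks (4.92%) in 603 genes, where evenly spread p-values would give 654. At p under 0.01 there were 188 peaks (95% Poisson interval 162 to 217) against 131, and at p under 0.001 there were 36 (25.2 to 49.8) against 13.1, in the authors' deposited table. The deposited p-values were not evenly spread, with 1560 peaks at 0.95 or more and a median of 546 per bin of 0.05 between 0.05 and 0.5. Of the 644, 471 were positive and 173 negative (73.1% positive), and 60.6% of all peaks were positive in the authors' deposited table. Among the largest differences the balance was the other way in the authors' deposited table, with 31 peaks at 1 or more and 58 at -1 or less, whatever their p. Among m6A genes, peaks in Wtap, Zc3h13 and Eif3a had 0.24, 0.23 and 0.16, and 1 in Ythdf1 (chromosome 2, 180910881 to 180911030) had -0.88 in the authors' deposited table, all at an FDR above 0.05. Of bone genes, the authors' deposited table held a called peak in Spp1 (0.15) and none in the osteoclast and Wnt lists. The osteocyte list had called peaks in 2 of 7 genes in the authors' deposited table, Mepe (0.13) and Dmp1 (0.02). Other called peaks of skeletal and signalling lists lay in Col9a1 (0.74), Col11a1 (0.27), Col3a1 (0.21) and Smad7 (0.61) in the authors' deposited table, named like those of osteocytes after their values were seen. None of 26 lists was enriched for called peaks after adjustment (smallest adjusted Fisher's exact p = 0.077, for 3 of 5 erythroid and 3 of 5 muscle genes), and 2 had an unadjusted p under 0.05. Genes with more peaks had more chances of a call. The 5 erythroid genes held 17 peaks and the 5 muscle genes 22, against a mean of 1.91 per gene. Neither these tests nor the main overlap with RNA corrected for that.

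**Figure D3:**
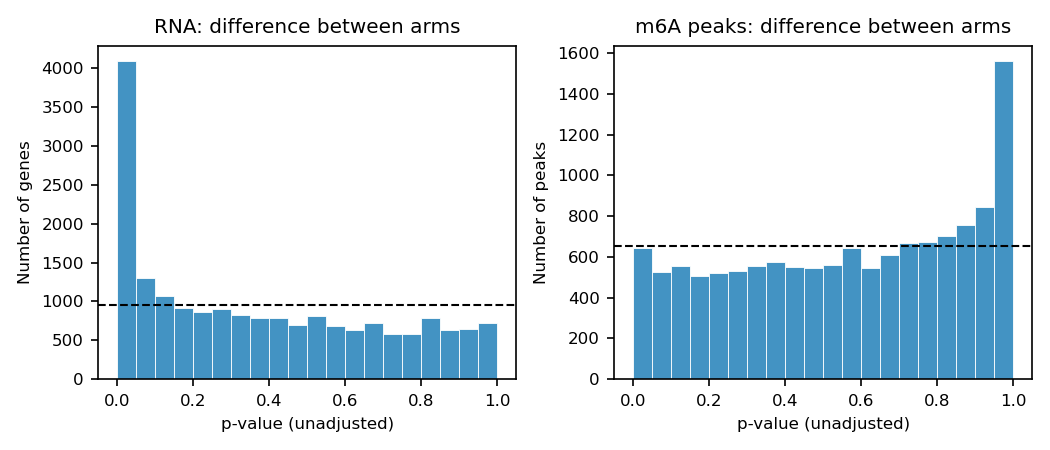
Number of genes (RNA) and of peaks (m6A difference) by deposited p-value in 20 bins, with a dashed line at the number that evenly spread values would give. The lowest bin held 4090 genes and 644 peaks.

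No excess of RNA changes was detected among genes with an m6A difference. Of 6824 genes in both tables, 601 had a called peak, 949 an RNA call and 94 both, against 83.6 expected of independent lists (odds ratio 1.16, two-sided Fisher's exact p = 0.195). By signs, 21 genes called in both tables were positive in both (30.2 expected), 38 had positive m6A and negative RNA (30.9), 19 had negative m6A and positive RNA (11.1) and 16 were negative in both (11.4). The adjusted Fisher's exact p-values were 0.158, 0.176, 0.073 and 0.176. The unstated numerator may differ between the m6A and RNA values, so equal signs need not mean equal directions. Across genes, which are not independent replicates, Spearman's rho of the m6A and RNA values was -0.02 and Pearson's r -0.01, and with the mean over a gene's peaks -0.06 and -0.05. Both tables share the input libraries, which alone can relate them, and this could not be simulated without per-library values.

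The m6A calls of the genes named next all had an FDR above 0.05, the lowest being 0.261 in Trdn. Positive in both were Dtx3l (m6A 0.94, RNA 0.60), Cers6, Cecr2 and Ubl5 in the authors' deposited tables. Several genes of muscle had negative RNA in the authors' deposited tables, with m6A of 0.38 in Trdn and 0.12 in Cmya5 and of -0.26 in Dmd and -0.52 in Fbxo40. Map7d3 (m6A 1.52, RNA -0.78) and Fzd7, a Wnt receptor (0.89 and -0.65), also had opposite signs in the authors' deposited tables. Rnf213 (-0.84 and 0.73), Pgm2l1 (-1.25 and 0.32) and Tuba4a had negative m6A and positive RNA in the authors' deposited tables. A2m (-0.64 and -3.22) and Myh14 were negative in both in the authors' deposited tables. A peak was present in 949 of 1875 changed genes (50.6%) and in 5875 of 13521 others (43.5%; odds ratio 1.33). Within 10 classes of the mean count the odds ratio was 0.94 (95% interval 0.85 to 1.04).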

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

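Alternatives at an adjusted p under 0.01, without the muscle list, at the authors' FDR, and those of the list tests were chosen after seeing the data. Changed genes numbered 392 (94 positive, 298 negative) with an absolute log2 fold change of at least 1, 4090 (1915 and 2175) at an unadjusted p under 0.05, and 882 (488 and 394) at an adjusted p under 0.01, against 1875 (934 and 941). The filters gave 1736 calls (1706 shared) with every gene and 1898 (1824 shared) at a mean of at least 50. Called peaks numbered 188 at p under 0.01, 15 with an absolute log2 difference of at least 1 and 3 at the authors' FDR, against 644. Among longer peaks 6.49% were called, against 4.92%, and counted per gene 50.8% had a peak over several exon blocks, against 40.1% per peak. The cause of these last shifts was not tested. The overlap of m6A and RNA calls missed the threshold in both other settings, with odds ratios of 1.42 (mean over peaks, Fisher's exact p = 0.058) and 1.18 (unadjusted RNA p, 0.079), and rho across genes was -0.063 with the mean over peaks, against -0.025. Of the list results under 4 other settings, 111 kept their side of the threshold, 7 lost and 2 gained a call. No paired analysis was possible because the tables hold no per-library values, and for the same reason left-out libraries, other tests, normalizations and an estimated correlation were not run.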

Other observations

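The tests of hypotheses in this part were chosen after the results were seen, except the test of the osteoclast list. Among genes outside the lists, also chosen after their values were seen, the smallest adjusted p in the authors' deposited table belonged to Otub2, a deubiquitinase, with 1.25 ± 0.10 (adjusted p = 2.8e-35). Gse1 followed with 0.59 ± 0.05, and Rab3d, a GTPase of secretory vesicles, stood at -2.07 ± 0.20 in the authors' deposited table. Pou2af1, Siglecg and Syk, which act in B cells, stood at 1.27 ± 0.21, 0.83 ± 0.12 and 0.63 ± 0.09 in the authors' deposited table. Fbxo32 and Trim63, ubiquitin ligases of muscle atrophy, stood at -2.20 ± 0.38 and -2.48 ± 0.60 and the growth inhibitor Mstn at -2.16 ± 0.52 in the authors' deposited table, below the muscle list's median of -1.28.

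A hypothesis is that positive values mean higher after ovariectomy, as the alphabetical order of the groups would give. Estrogen is known to restrain B cell formation, so a B cell median of 1.06 and Greb1 at -2.35 go with that reading. The osteoclast list, which resorption after ovariectomy would raise, missed the threshold (cameraPR adjusted p = 0.197), and Ctsk, its only changed gene, stood at -0.72. These values leave the direction open, as no sample values were at hand.

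Muscle genes were negative with wide errors. Unequal amounts of muscle left on the bone would give all members 1 fold change. All 17 members lay within 1 SE of the median, but the median SE of 0.605 exceeds the spread between members (SD 0.256), so this could hardly have come out otherwise and decides nothing. Fbxo32 and Dmd, muscle-expressed genes outside the list chosen after their values were seen, stood at -2.20 ± 0.38 and -2.05 ± 0.32 in the authors' deposited table, beyond the list's median of -1.28. Klf15, chosen in the same way, stood at -1.25 ± 0.35, near that median. Unequal amounts of muscle and a change of muscle after ovariectomy both stay open.

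Of the peaks, 60.6% (59.8 to 61.5) lay on the plus strand of the genome. The excess held on 20 of 20 chromosomes, from 53.4% to 67.9%. Counted over genes with a peak, the plus-strand share was 58.2%. Among such genes it was 70.2% (66.6 to 73.6) in the lowest of 10 classes of mean count and 52.4% (48.6 to 56.2) in the highest. That difference goes against a plus-strand share that is alike at all mean counts. The share among genes without a peak is not given here, so an excess of plus-strand genes stays open. Strand-dependent peak finding in the processing is a candidate explanation. Plus-strand peaks also had a median log2 difference of 0.07 against 0.02 on the minus strand and were called more often (5.37% against 4.23%).

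Low counts were heaped. Of 955 genes whose mean count under 4 was a multiple of 1 library's step, within 2e-07 per count, 284 stood at 4 counts in that library. From 1 to 3 counts there were 94, 104 and 110 genes, and from 5 to 9 counts 42, 60, 77, 76 and 22. With 1 count per fragment most would stand at 1 count, and the 308 genes at 1 to 3 counts argue against exactly 4 counts for every fragment. The drops after 4 and after 8 leave open that 1 fragment was entered as up to 4 counts, as conversion of StringTie coverage with too short a read length could give, and the sum of 43717045 counts would then stand for at least 10929261 fragments per library. The low mean counts of Zic1, Tppp2, Mir12191 and Efcab6 would then also stand for fewer fragments. No biological explanation was tested for the strand and count patterns.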
